A study of Mus musculus with 12 samples.

How the data were processed

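RNA of primary neuronal cultures was hybridised to 12 whole-transcript Affymetrix arrays, 2 for each of 6 groups: control, amitriptyline, citalopram, duloxetine, imipramine and mirtazapine. Group and replicate number were taken from the labels' titles, and doses and times from the labels' protocols. The deposited values are on a log2 scale, rounded to 2 decimals, for 41345 probe sets; the authors made them with Affymetrix Expression Console and RMA (background correction, quantile normalization and probe summarisation), per the submitters' processing notes. Versions, settings and a genome build are not given in the sources used here, and no coordinates are printed. RMA values carry no counts, so no depth can be stated, and the number of arrays per group (2) limits the precision.

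Probe sets were named from the platform annotation: 23521 had 1 gene symbol, 1814 had several and 16010 had none. Of those with 1 symbol, 99.2% matched the GRCm38 gene table by gene number, and 0 symbols changed. A gene was represented by its probe set of highest mean, and kept where the mean log2 over all arrays reached the 30th percentile of all probe sets (5.72), which left 17467 of 22180 named genes. Ntf3 had no probe set with exactly 1 symbol, and Gdnf lay below the filter, so neither is analysed here. Some genes of the fixed set are not reported here.

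All 12 arrays entered 1 linear model in limma 3.58.1 (R 4.3.3; lmFit and eBayes without trend), with 6 residual degrees of freedom and 3.86 prior ones. Each drug was compared with control, the mean of the 5 drugs with control, the 5 drugs with each other (F test) and each of the 10 drug pairs. P-values were adjusted by Benjamini-Hochberg over the 17467 genes of a comparison and called under 0.05; intervals are 95% intervals from the same fit, with tests of both directions. In data simulated from the real means and spreads for mirtazapine against control, the fit over 17467 genes recovered 20.9% of genes changed by 0.5 log2 units, 82.1% of those changed by 1 and 98.5% of those changed by 2. This was a single draw with 67, 67 and 66 changed genes of these sizes. It gave all arrays the same spread for a gene. Duloxetine replicate 2 and mirtazapine replicate 2 in fact varied more (residual SD 0.298 and 0.301, against 0.099 to 0.174 elsewhere), so these shares are only a rough guide.

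Gene lists of pathways, cell functions and cell type markers (29 lists) were written before the data were examined, as were the design, the alternatives and the rule for named genes. Of these lists 28 had at least 5 tested genes, and the list of erythroid markers was not tested. Lists were tested with camera (preset correlation 0.01), adjusted over 140 combinations of 28 lists and 5 drugs. Camera called 52 of the 140. None of the 52 held with an estimated correlation (lowest adjusted p = 0.132), and fry, which tests whether a list's genes move on balance in 1 direction, called 10. List means and their intervals come from limma on the mean of a list's genes per array. Counts given for a list alone adjust p over its own genes.

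Named genes are, per drug, the 8 rising and 8 falling called genes of lowest p and, where fewer than 8 passed, the lowest p-values up to 8, plus a fixed set of trophic, activity, stress, sterol and cell type genes and the members of a described list that pass over the list alone. For the other tests the 8 genes of lowest p are named, and the 9th gene called for the mean of the drugs, Pla2g2e, falls outside that rule for this test and was named after its values were seen. Predicted genes, clones and small RNAs were passed over. Gpr17 and Cspg4, named under duloxetine without passing over their list, and the 5 genes called under imipramine where they are given for other comparisons, were chosen after their values were seen. Nptx1, Nts, Nrp1 and Nrp2 are named as members that pass over their lists.

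All comparisons with control share the same 2 arrays, so overlaps and correlations between drugs are set beside 100 simulated draws of unchanged groups. Where an array was left out, the lone array of its group was assumed to vary like those of the other groups. Alternatives tried were no filter, a 50th percentile filter, every probe set, eBayes with trend and robust, array weights, a second quantile normalization, a replicate block, a minimum log2 difference of 0.5, each array left out in turn, and only the 4 arrays of the groups compared. Leaving out both arrays that stand apart, and giving each drug of a pair, or the picking and the measuring of genes, 1 control array of its own, were added after seeing the data. Figures were drawn with matplotlib 3.10.9 (Python 3.11.15).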

Results

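Transcript levels were measured on Affymetrix arrays in primary neuronal cultures from the brains of ICR (CD-1) mouse embryos, an outbred laboratory stock. Cultures were given an antidepressant at day in vitro 3 and harvested 48 h later, at day in vitro 5. The drugs were the tricyclics amitriptyline (5 µM) and imipramine (5 µM), the selective serotonin reuptake inhibitor citalopram (10 µM), the serotonin and noradrenaline reuptake inhibitor duloxetine (0.1 µM) and the tetracyclic mirtazapine (50 µM). Each of the 5 drug groups and the control group had 2 arrays, 12 in all, and 17467 genes were tested. The number of arrays limits the precision: the 95% interval of a drug-control difference reached 0.28 log2 units to either side for the median gene. The labels do not say whether replicates came from separate cultures or animals, so p-values measure only the spread between these samples. What the control cultures received is not given in the sources used here.

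Along the second principal component, which held 14.5% of the variance, the control and duloxetine arrays lay together, between −15.2 and −5.8. Those of amitriptyline, imipramine and mirtazapine lay between 2.7 and 10, and the citalopram arrays at −0.7 and 2.6. The first component (52.5%) set 2 arrays apart, duloxetine replicate 2 at 32.6 and mirtazapine replicate 2 at 36.4, where the highest of the other 10 was 3.9. Regressed on the mean of the other arrays, these had slopes of 0.912 and 0.899, against 0.979 to 1.014 elsewhere. They correlated more with each other (r = 0.9873 across genes) than with the second array of their own drug (0.9784 and 0.9845). Both arrays enter the spread pooled over all groups, which tends to raise the p-values and widen the intervals of comparisons between the other groups.

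**Figure D1:**
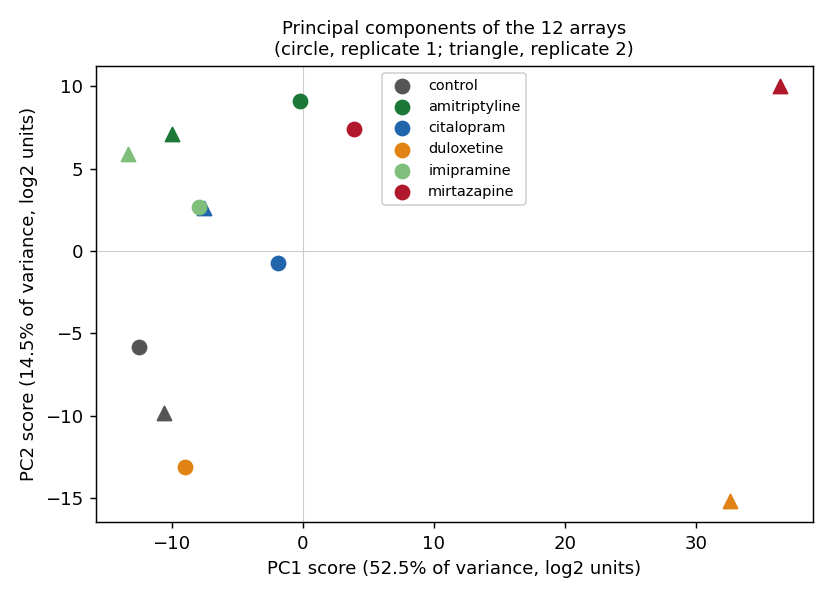
Scores of the 12 arrays on the first (x axis) and second (y axis) principal components of log2 expression, coloured by group, with circles for replicate 1 and triangles for replicate 2. Duloxetine 2 (32.6) and mirtazapine 2 (36.4) lie apart on the first component, and control and duloxetine arrays share the lower part of the second.

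The first question was which genes responded to each drug. Imipramine raised 5 genes and lowered 0 at an adjusted p under 0.05 in limma. Ptgs2, the inducible prostaglandin synthase, rose from a mean log2 of 7.78 ± 0.47 (SD, n = 2) in control to 10.15 ± 0.3 (n = 2), a 5.17-fold increase (log2 difference 2.37 ± 0.25 SE, adjusted p = 0.0221). Ostn, encoding the secreted peptide osteocrin, rose 2.9-fold (adjusted p = 0.0221), and the chemokine gene Cxcl2 rose 2.76-fold (adjusted p = 0.0471). Hmox1, the inducible heme oxygenase, rose 2.44-fold (adjusted p = 0.0388), and the early response gene Ier3 rose 1.94-fold (adjusted p = 0.0156). All of these were above both control arrays on both imipramine arrays. The phospholipase gene Pla2g2e (log2 difference 0.88, adjusted p = 0.0538), Steap1 (1.00, adjusted p = 0.054) and Tmem100 (−0.97, adjusted p = 0.0576) came next without passing.

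Few members of the gene lists passed singly under imipramine, but several lists shifted. Of 36 cell cycle genes, 35 had negative differences (median −0.39; mean −0.38, 95% interval −0.57 to −0.20), and 19 fell adjusted over the list alone, against 0 over all genes. Examples are Ccnb2 (−0.52), Nusap1 (−0.75) and the proliferation marker Mki67 (−0.67). The camera test called this list (adjusted p = 2.03e-28), but not with an estimated correlation (adjusted p = 0.176). All 18 astrocyte markers had negative differences (median −0.31, camera adjusted p = 1.09e-16, and adjusted p = 0.132 with an estimated correlation), 9 of them fell adjusted over the list alone, and the largest was that of the water channel gene Aqp4 (−0.93). Every one of 27 integrated stress response genes had a positive difference (median 0.25, camera adjusted p = 6.66e-25, and adjusted p = 0.176 with an estimated correlation). Adjusted over the list alone, 3 rose: the stress regulator Nupr1 (1.00), Ppp1r15a (0.64), encoding a regulatory subunit of an eIF2α phosphatase, and the cystine transporter gene Slc7a11 (1.39). Of 23 NRF2 antioxidant genes, 18 had positive differences (median 0.13, camera adjusted p = 4.27e-10, and adjusted p = 0.199 with an estimated correlation), and 7 rose adjusted over the list alone, among them Hmox1, Srxn1 (1.15) and the quinone reductase gene Nqo1 (0.72). Camera also called the NRF2 list under amitriptyline (median 0.095, adjusted p = 0.000331) and citalopram (0.06, adjusted p = 0.000416), but under neither with an estimated correlation. With any 1 array of amitriptyline, citalopram or imipramine, or control replicate 1, left out, imipramine had 0 calls in limma. There were 21 without control replicate 2, 29 without either duloxetine array, and 84 without both arrays that stand apart, the 5 genes among them.

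Under amitriptyline 0 of 17467 genes passed in limma: the lowest adjusted p was 0.0542, with 1073 genes at an unadjusted p under 0.05. The 8 genes of lowest p shared that adjusted value and included Ptgs2 (log2 difference 2.07 ± 0.25 SE, 4.2-fold), Ostn (1.33), Hmox1 (1.28), Steap1 (1.01), Pla2g2e (0.84) and Ier3 (0.80). The astrocyte genes Aqp4 (−1.03 ± 0.14) and Gfap (−0.71 ± 0.10), the latter encoding glial fibrillary acidic protein, were the negative ones. Among 36 cell cycle genes 34 had negative differences (median −0.51, mean −0.47, 95% interval −0.66 to −0.29), and 26 fell adjusted over the list alone, Cdk1 (−0.92) and Top2a (−0.91) among them. Camera called that list at an adjusted p of 1.16e-28, and adjusted p = 0.176 with an estimated correlation. Astrocyte markers were negative for 17 of 18 (median −0.29, camera adjusted p = 5.34e-15, and adjusted p = 0.132 with an estimated correlation), with 11 that fell adjusted over the list alone. Integrated stress response genes were positive for 27 of 27 (median 0.22, camera adjusted p = 6.82e-17, and adjusted p = 0.176 with an estimated correlation). Over the alternatives this median ranged from 0.115 to 0.25, and that under imipramine from 0.16 to 0.295. The control arrays themselves lay at −0.099 (replicate 1) and 0.099 (replicate 2) around their mean for this list. The count of 0 became 17 without control replicate 2, 48 without either duloxetine array, and 228 (56 higher, 172 lower) without both arrays that stand apart.

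Under citalopram 0 genes passed in limma (lowest adjusted p 0.0917; 776 genes at an unadjusted p under 0.05). Its lowest p-values again belonged to Ptgs2 (log2 difference 2.14 ± 0.25 SE, 4.39-fold, adjusted p = 0.0917) and Ier3 (0.72 ± 0.09, adjusted p = 0.0917). They were followed by Hmox1 (1.14, adjusted p = 0.151), the cyclin gene Ccnb2 (−0.61, adjusted p = 0.183), Tmem100 (−0.88, adjusted p = 0.183), the replication factor gene Pclaf (−0.71, adjusted p = 0.183), Cxcl2 (1.19, adjusted p = 0.186) and the Notch target Hes5 (−0.73, adjusted p = 0.193). The cell cycle list had 35 of 36 negative differences (median −0.39, camera adjusted p = 3e-28, and adjusted p = 0.176 with an estimated correlation) and 19 genes that fell adjusted over the list alone. All 27 integrated stress response genes were positive (median 0.29, camera adjusted p = 1.38e-25, and adjusted p = 0.176 with an estimated correlation), with 9 that rose adjusted over the list alone. Leaving out control replicate 2 gave 10 calls.

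Mirtazapine, given at the highest concentration, changed 304 genes in limma, of which 47 rose and 257 fell. The genes of lowest p fell. They were Tacr3, the neurokinin 3 receptor (log2 difference −1.56 ± 0.13 SE, adjusted p = 0.0056), the neuropeptide genes Cck (−1.17 ± 0.10, adjusted p = 0.0056) and Grp (−0.98 ± 0.10, adjusted p = 0.00681), and Calb2, encoding the calcium-binding protein calretinin (−1.38 ± 0.14, adjusted p = 0.00751). Lpl, the lipoprotein lipase gene (−1.25), Hes5 (−1.14), the zinc finger gene St18 (−0.79) and Itgbl1 (−0.95) also fell. A second, dimmer probe set of Hes5 was at −0.07, and that of Lpl at −0.82. Genes that rose were Ptgs2 (1.79 ± 0.25, 3.46-fold), Hmox1 (1.16, 2.23-fold), Ostn (1.10), the collagen receptor gene Ddr2 (1.00), G6pc (0.71), Ier3 (0.68), Dntt (0.58) and the vascular growth factor gene Vegfa (0.55), with adjusted p between 0.0145 and 0.0205. On control replicates 1 and 2, G6pc (log2 5.6 and 5.76) and Dntt (5.78 and 5.76) lay near the filter of 5.72. Both were highest on mirtazapine replicate 2, at 0.77 and 0.7 above the control mean, against 0.66 and 0.47 on replicate 1. Over all probe sets mirtazapine replicate 2, which stands apart, had the highest lower quartile of the 12 arrays (5.57, against 5.42 and 5.39 in control replicates 1 and 2). Its upper quartile was the lowest (8.2, against 8.37 and 8.36), so dim probe sets as a whole read higher on this array. How far this raised G6pc and Dntt was not tested. Among the always-named genes Atf3 (0.87, adjusted p = 0.0228) rose, and Gfap (−0.60, adjusted p = 0.0214) and Mki67 (−0.68, adjusted p = 0.049) fell.

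Of 36 cell cycle genes 12 fell over all genes under mirtazapine and 29 adjusted over the list alone (median −0.62, mean −0.56, 95% interval −0.75 to −0.37, camera adjusted p = 4.46e-15, and adjusted p = 0.381 with an estimated correlation). Of 18 astrocyte markers 5 fell over all genes and 13 adjusted over the list alone (median −0.34, camera adjusted p = 9.98e-06, and adjusted p = 0.199 with an estimated correlation), while 1 rose adjusted over the list alone. Oxidative phosphorylation genes were negative for 48 of 51 (median −0.21, camera adjusted p = 1.62e-06, and adjusted p = 0.422 with an estimated correlation), and 12 fell adjusted over the list alone, Cox5a (−0.53) and Ndufa9 (−0.53) among them. Camera also called this list lower under citalopram (median −0.065, adjusted p = 0.00262) and duloxetine (−0.1, adjusted p = 0.00951), but under neither with an estimated correlation. Its mean lay at −0.013 in duloxetine replicate 1 and −0.182 in replicate 2, which stands apart. Under mirtazapine, integrated stress response genes had 23 positive differences of 27 (median 0.22, camera adjusted p = 1.27e-06, and adjusted p = 0.422 with an estimated correlation), and 8 rose adjusted over the list alone. Within the neuropeptide list Cck, Nts (−1.79, encoding neurotensin) and Nptx1 (−0.64) fell over all genes, but the median of its 26 genes was 0.06 and the mean −0.08 (camera adjusted p = 0.936). Camera called that list lower under amitriptyline (median −0.08, adjusted p = 0.0294, and adjusted p = 0.4 with an estimated correlation) and duloxetine (median −0.19, adjusted p = 0.045, and adjusted p = 0.422 with an estimated correlation). The first call ended without amitriptyline replicate 1 (−0.082), control replicate 1 (−0.047) or either duloxetine array (−0.078), and the second without control replicate 1 (−0.13), duloxetine replicate 1 (−0.152) or either mirtazapine array (−0.19). The axon guidance receptor genes Nrp1 (−0.93) and Nrp2 (−1.12) fell, and 8 of the 42 genes of their list fell adjusted over the list alone (median −0.10, camera adjusted p = 0.0268, and adjusted p = 0.904 with an estimated correlation). That list's call ended without either duloxetine array (median −0.10) or without mirtazapine replicate 2 (−0.02). Without mirtazapine replicate 2, which stands apart, 8 genes were called, and 1450 without mirtazapine replicate 1. Leaving out control replicate 1 left 0 and control replicate 2 left 116, against 139, 66 and 148 without an amitriptyline, citalopram or imipramine array, and 1328 without either duloxetine array; without both arrays that stand apart, 370 were called, 224 of the 304 among them. With array weights mirtazapine had 110 calls, against 222 for amitriptyline and 128 for imipramine, so the order of the drugs by number of calls turns with the setting. Quantile normalized again, mirtazapine had 348 calls, of which 82 rose.

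Radial glia and progenitor markers were lower along with the cell cycle and astrocyte lists, while endothelial and microglia markers were higher under mirtazapine. The 16 radial glia and progenitor markers had medians of −0.13 under amitriptyline, −0.12 under citalopram, −0.10 under imipramine and −0.21 under mirtazapine (camera adjusted p = 0.00291, 0.00524, 0.00977 and 0.0101, and adjusted p = 0.176, 0.176, 0.199 and 0.199 with an estimated correlation). Hes5 and the transcription factor gene Pax6 (−0.42 under mirtazapine) fell adjusted over the list alone. The call under imipramine ended without imipramine replicate 1 (median −0.11). Under mirtazapine endothelial markers were higher (median 0.22, camera adjusted p = 0.0193, and adjusted p = 0.657 with an estimated correlation), as were microglia and macrophage markers (median 0.17, camera adjusted p = 0.0367, and adjusted p = 0.745 with an estimated correlation). The endothelial call ended without control replicate 1 (median 0.17) or mirtazapine replicate 2 (0.125). The microglia call ended without control replicate 2 (median 0.052), mirtazapine replicate 1 (0.185) or mirtazapine replicate 2 (0.093).

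**Figure D2:**
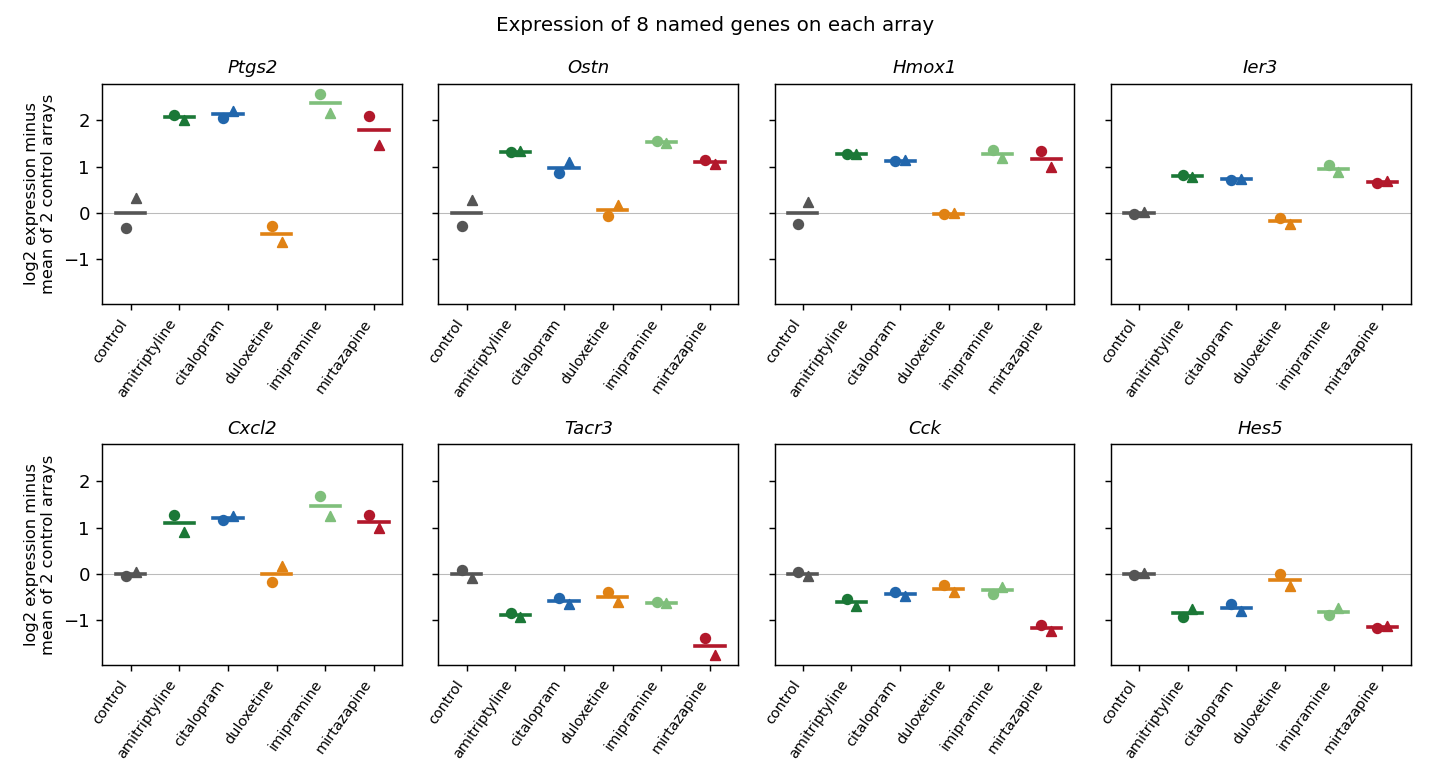
Log2 expression of 8 named genes on each of the 12 arrays, less the mean of the 2 control arrays (y axis), by group (x axis), with circles for replicate 1, triangles for replicate 2 and bars for group means. Ptgs2 lies at means of 1.79 to 2.37 under 4 drugs and at −0.45 under duloxetine, and Tacr3 and Cck are lowest under mirtazapine (−1.56 and −1.17).

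Duloxetine, given at the lowest concentration, called 0 genes in limma (lowest adjusted p 0.492; 1754 genes at an unadjusted p under 0.05). The genes raised by imipramine had differences near or below 0: Ptgs2 −0.45 ± 0.25 (SE), Ier3 −0.17 ± 0.09, Hmox1 −0.01 ± 0.15, Cxcl2 −0.01 ± 0.18 and Ostn 0.06 ± 0.17. Genes of lowest p, all at an adjusted p of 0.492, were Bcl6b (−0.53), the keratin gene Krt18 (0.65), the polarity gene Pard6a (−0.42), Barx2 (0.55), Fmr1nb (0.51), Cyp2d40 (0.77), Nat8f3 (0.45) and Selenom (−0.46). The immediate early list was lower, with 27 of 34 genes negative (median −0.22, camera adjusted p = 8.85e-06, and adjusted p = 0.4 with an estimated correlation); the activity-dependent genes Fos (−0.85) and Npas4 (−0.96) did not pass singly, and their control arrays differed widely (SD 0.67 and 0.75, n = 2). Camera no longer called the list without duloxetine replicate 1 (median −0.24). Oligodendrocyte lineage markers were positive for 13 of 14 (median 0.28, camera adjusted p = 0.000133, and adjusted p = 0.424 with an estimated correlation), Gpr17 (0.77) and Cspg4 (0.36) among them. Over the alternatives that median ranged from 0.152 to 0.395, and the list's median under amitriptyline from −0.333 to −0.163. The list means of control replicates 1 and 2 lay at −0.16 and 0.16 around their mean, and those of duloxetine replicates 1 and 2 at 0.2 and 0.375, so control replicate 2 was near duloxetine replicate 1. Camera also called endothelial markers (median 0.15, adjusted p = 0.00998, and adjusted p = 0.616 with an estimated correlation) and fibroblast and pericyte markers (median 0.13, adjusted p = 0.0219, and adjusted p = 0.544 with an estimated correlation) higher under duloxetine. Both lists had higher means in duloxetine replicate 2, the array that stands apart (0.268 and 0.264), than in replicate 1 (0.07 and 0.036). Both calls ended without duloxetine replicate 2 (medians 0.095 and 0.01) and without control replicate 1 (0.13 and 0.09). Under the tricyclics and citalopram the oligodendrocyte list was lower: its median was −0.27 under amitriptyline, −0.12 under citalopram and −0.19 under imipramine, with camera adjusted p of 6.82e-06, 0.00057 and 1.13e-05, and adjusted p of 0.4, 0.507 and 0.4 with an estimated correlation. Under mirtazapine its median was −0.24 without a call (camera adjusted p = 0.26). Without control replicate 2 the calls under citalopram (median −0.07) and imipramine (−0.09) ended, and mirtazapine gained a call without control replicate 1 (−0.32) or mirtazapine replicate 2 (−0.21). Cell cycle genes under duloxetine had a median of −0.19 and a mean of −0.19 (95% interval −0.37 to 0.00, camera adjusted p = 0.000162, and adjusted p = 0.69 with an estimated correlation), and without both arrays that stand apart the mean was −0.02 and camera's adjusted p = 0.594. Without duloxetine replicate 1, which leaves only the array that stands apart, 2040 genes were called.

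**Figure D3:**
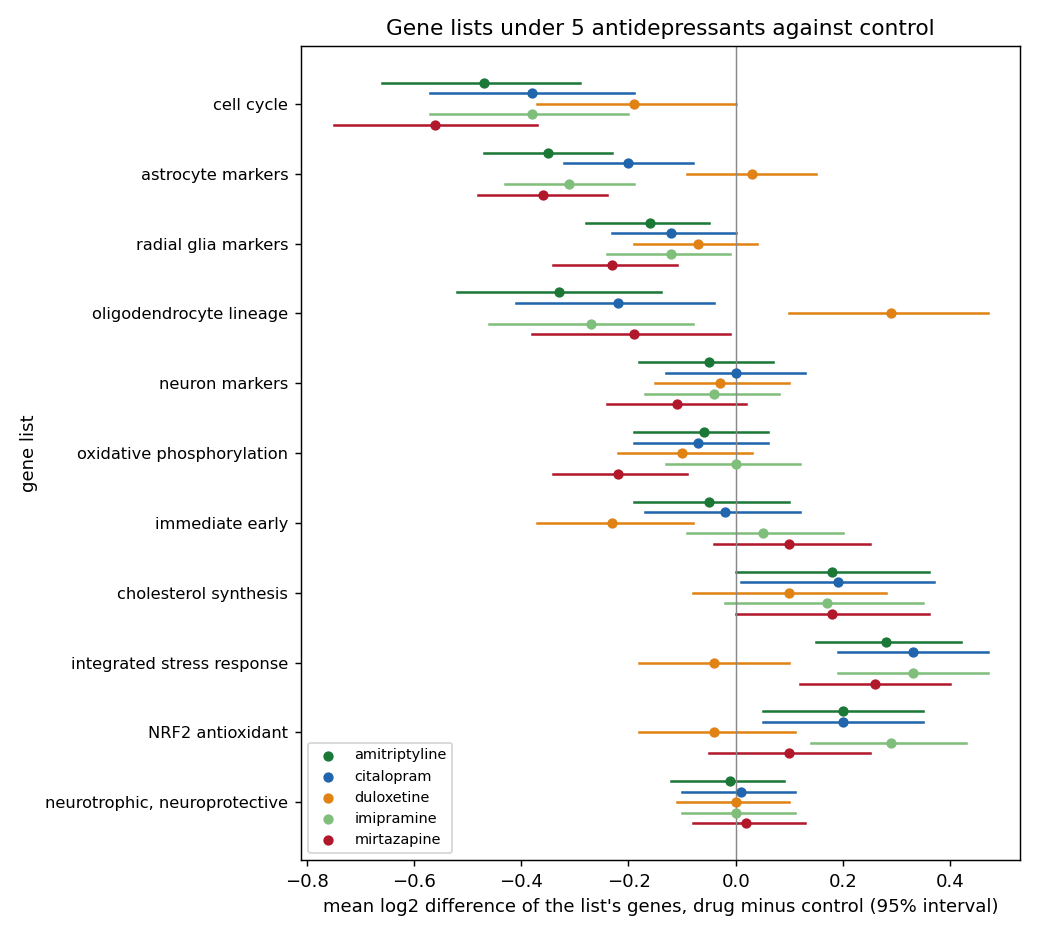
Mean log2 difference of each gene list, drug minus control (x axis), with its 95% interval, for 11 lists (y axis) and 5 drugs in colour. The cell cycle mean lies between −0.56 and −0.38 under 4 drugs and at −0.19 under duloxetine, and neuron markers lie between −0.11 and 0.00.

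The title of the series names epigenetic effects on neuroprotective genes as its subject. Bdnf, the brain-derived neurotrophic factor gene, showed no detectable change: its log2 differences were 0.02 under amitriptyline, 0.03 under citalopram, 0.11 under duloxetine, 0.08 under imipramine and 0.15 under mirtazapine, each ± 0.12 (SE), with adjusted p from 0.423 to 1. The secreted neuropeptide precursor gene Vgf lay between −0.46 (duloxetine) and 0.14 (mirtazapine) without passing. The 37 neurotrophic and neuroprotective genes had medians from −0.03 to 0.04 and camera adjusted p from 0.351 to 0.858; Hmox1, which 2 drugs raised, and Vegfa, raised by mirtazapine, belong to this list, while Hgf, the hepatocyte growth factor gene, fell under mirtazapine (−0.99, adjusted p = 0.0436). Chromatin regulators (59 genes) had medians from −0.06 to 0.00, with camera adjusted p of at least 0.223; Hdac5 lay between −0.12 and 0.14 and Rest between −0.08 and 0.09, none passing. The neuronal gene Map2 lay between −0.09 and 0.02, the microglial gene Aif1 between −0.32 and −0.09, and the serotonin transporter gene Slc6a4 between −0.65 (amitriptyline, adjusted p = 0.252) and −0.26 (duloxetine).

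Set as 1 group against control, the 5 drugs changed 9 genes in limma. Ptgs2 (mean difference 1.58 ± 0.20 SE), Ostn (1.00), Hmox1 (0.97), Pla2g2e (0.67) and Ier3 (0.60) rose, and Tacr3 (−0.83), Tmem100 (−0.82), Aqp4 (−0.81) and Hes5 (−0.73) fell, with adjusted p between 0.0345 and 0.0417. A changed mean need not be shared by every drug. Under duloxetine Ptgs2 (−0.45), Ier3 (−0.17), Hmox1 (−0.01) and Ostn (0.06) were not raised, and Aqp4 (−0.15) and Hes5 (−0.13) differed little. Pla2g2e (0.28), Tmem100 (−0.39) and Tacr3 (−0.5) moved with the mean. The second, dimmer probe set of Hes5 lay between −0.15 (imipramine) and 0.23 (duloxetine). Leaving out control replicate 1 or any amitriptyline, citalopram or imipramine array ended all calls, and 46 were made without control replicate 2, 243 and 72 without duloxetine replicate 1 or 2, 1 and 3 without mirtazapine replicate 1 or 2, and 206 without both arrays that stand apart, including the 9.

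The drugs were also compared with each other, where the control arrays enter only through the pooled spread. An F test across the 5 drugs found 2 genes that differed, Ier3 (adjusted p = 0.0288) and Ptgs2 (adjusted p = 0.0318), both lowest under duloxetine; Hmox1, Ostn, Cck, Tacr3, Mlc1 and Bgn followed at an adjusted p of 0.116. Between drug pairs, 83 genes differed between duloxetine and mirtazapine (60 higher and 23 lower under duloxetine) and 21 between duloxetine and imipramine (1 higher and 20 lower under duloxetine). Amitriptyline and citalopram each differed from duloxetine in 2 genes. The doses of these pairs differ, and duloxetine's was the lowest. Without both arrays that stand apart the F test called 0 genes, duloxetine and mirtazapine differed in 61 genes (31 shared), duloxetine and imipramine in 25 (13 shared), amitriptyline and duloxetine in 54 and citalopram and duloxetine in 0 (1577 genes at an unadjusted p under 0.05). Single arrays moved these counts widely. Leaving out an amitriptyline, citalopram or imipramine array, or duloxetine replicate 2, ended the calls of the F test, while either control array left 5 and duloxetine replicate 1 left 76. Duloxetine and mirtazapine differed in 1 gene without mirtazapine replicate 2, 6 without duloxetine replicate 1, 148 without duloxetine replicate 2, 42 without a control array, and 7, 0 and 18 without an amitriptyline, citalopram or imipramine array. Duloxetine and imipramine differed in 2349 genes without duloxetine replicate 1, 1 without duloxetine replicate 2, 2 without an amitriptyline or citalopram array or imipramine replicate 2, 0 without imipramine replicate 1, and 32 without either mirtazapine array. Amitriptyline and duloxetine differed in 1322 genes and citalopram and duloxetine in 442 without duloxetine replicate 1, and both pairs in 0 without duloxetine replicate 2 or an amitriptyline or citalopram array. Without a control array these pairs differed in 11 and 4 genes, and amitriptyline and duloxetine in 9 without a mirtazapine array.

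Amitriptyline and imipramine could be compared at a matched dose and time. Both carry a basic dimethylamino side chain on a tricyclic ring system, and the central ring atom bearing it is a nitrogen in imipramine, a dibenzazepine, and a carbon joined by an exocyclic double bond in amitriptyline. At 5 µM and 48 h, 0 genes differed in limma (lowest adjusted p 1; 211 genes at an unadjusted p under 0.05). The 95% interval of the difference lay within 1 log2 unit of 0 for 17384 genes (99.5%). Neither value was particular to this pair. At unmatched doses 0 genes also differed between amitriptyline and citalopram (229 at an unadjusted p under 0.05) and between citalopram and imipramine (189). The same held for mirtazapine against amitriptyline (1756), citalopram (1789) and imipramine (3083). The share of such intervals was 99.5% in both pairs of citalopram with a tricyclic, and 97.6% for amitriptyline and duloxetine. For Ptgs2 the difference, amitriptyline minus imipramine, was −0.30 (95% interval −0.86 to 0.26), for Ostn −0.21 (−0.58 to 0.16), for Cxcl2 −0.37 (−0.78 to 0.04), for Hmox1 −0.01 (−0.35 to 0.33) and for Gfap −0.20 (−0.42 to 0.02). Genes of lowest p, none passing, were Eif4a3l1 (0.63), Srsx (0.79), Cd109 (−0.56), Nqo1 (−0.47, 95% interval −0.72 to −0.23), Speer4c (0.40), Mettl7a1 (−0.41), Fes (0.37) and Atp6v1fnb (0.44). The cell cycle list differed by a mean of −0.09 (95% interval −0.28 to 0.10) and the astrocyte list by −0.04 (−0.16 to 0.08). A p that misses the threshold does not show that both drugs act alike: for Ptgs2 the interval reaches −0.86. The pooled spread also includes both arrays that stand apart (residual SD 0.298 and 0.301, against 0.099 to 0.174 elsewhere). They enlarge it, so the low counts among amitriptyline, citalopram and imipramine do not measure how far these drugs agree.

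**Figure D4:**
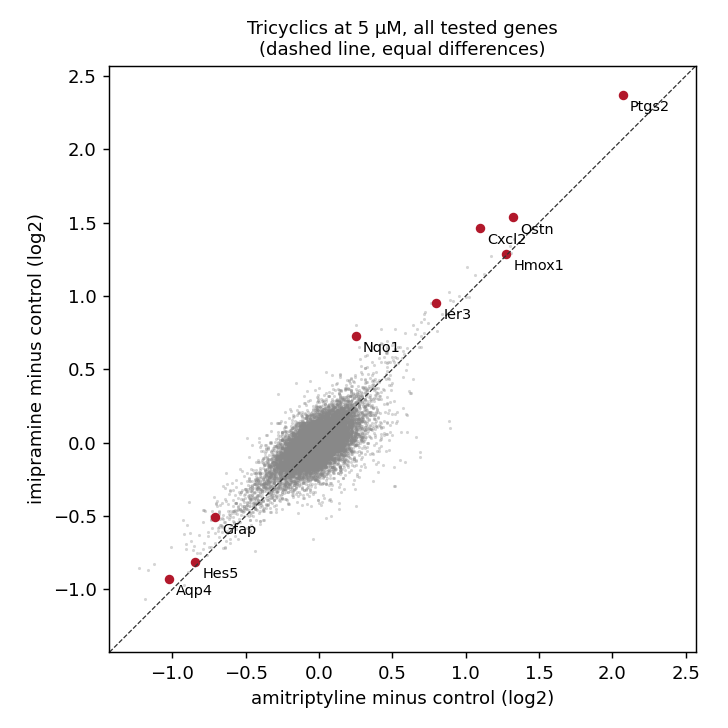
Log2 difference from control of every tested gene under amitriptyline (x axis) and imipramine (y axis), both at 5 µM, with 9 named genes in red and a dashed line of equal differences. Ptgs2 lies at 2.07 and 2.37, Aqp4 at −1.03 and −0.93, and Nqo1 above the line.

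Across genes, which are not independent replicates, the differences from control of amitriptyline and imipramine correlated at r = 0.72, against 0.5 in simulated groups with no effect that share the control arrays (mean of 100 draws). Their covariance was 0.0168 against 0.0129 simulated, and 559 genes had an unadjusted p under 0.05 in the same direction, against 228.8 simulated and 27.3 for independent lists. For amitriptyline and citalopram the covariance was 0.0171 against 0.0129 (r = 0.73), and for duloxetine and imipramine 0.0064 against 0.0129 (r = 0.21). The simulated spread includes both arrays that stand apart, which enlarges it. The simulation also gave all arrays the same spread for a gene, so its r of 0.5 follows from sharing 2 control arrays. Replicates of amitriptyline, citalopram and imipramine correlated at 0.9952 to 0.9968, against 0.9938 in control. Controls that vary more than the drug groups raise r without any effect, so the excess over 0.5 among these drugs may be overstated. The correlation of duloxetine with mirtazapine was 0.72 with all arrays and 0.31 without both. Of mirtazapine's 304 called genes, 301 had the same sign under amitriptyline, 303 under citalopram, 292 under imipramine and 271 under duloxetine, or 99, 99.7, 96.1 and 89.1%, where the 304 genes of lowest p in simulated groups gave 89.8 to 90%. Over all genes imipramine and mirtazapine shared their sign in 60.5%, below the simulated 66.7% (r = 0.44 against 0.5, and 0.58 without both arrays that stand apart), while their covariance was 0.018 against 0.0129 and 560 genes had an unadjusted p under 0.05 in the same direction, against 227.9 simulated and 96.8 for independent lists. The 2 control arrays do not leave each drug of a pair 2 of its own, so part of any excess may come from the shared controls. With 1 control array for each drug, in both assignments, the correlation was 0.23 and 0.33 for amitriptyline and imipramine, 0.18 and 0.42 for amitriptyline and citalopram, 0.19 and 0.21 for imipramine and mirtazapine, 0.46 and 0.6 for duloxetine and mirtazapine, and −0.12 and 0.04 for duloxetine and imipramine. The values for duloxetine and mirtazapine include both arrays that stand apart, which resemble each other, so they may reflect those arrays.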

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

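Probe sets without exactly 1 gene symbol take no part in the comparisons of named genes. Tested with every other probe set after the same filter, 3 of 10454 passed under mirtazapine (2 higher, 1 lower), a signal in data outside the main measurement. No explanation was tested for them.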

How the results depend on the processing

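Of the alternatives here, leaving out both arrays that stand apart was chosen after seeing the data, and the others were planned. Of the named genes' values under alternatives, 2896 kept their sign and side of the threshold, 65 changed sign or reached 0 with no call in either fit, 116 gained a call, 206 lost it and 0 changed sign with a call in either fit. Of the list values 2564 stayed, 136 changed sign or reached 0 with no call, 52 gained a call, 172 lost it and 11 changed sign, reached 0 or left it with a call. The cause of these changes was not tested, except that fewer arrays or another number of tested genes follow from an alternative's construction. By construction, too, leaving out an array of another drug keeps a drug's difference from control and alters only the estimated spread and its degrees of freedom. With no filter, imipramine had 3 calls, mirtazapine 191, the mean of the drugs 0 and the F test 0. With a 50th percentile filter amitriptyline had 17 and the mean 62. With every probe set imipramine had 0, mirtazapine 23, the mean 0 and the F test 0. With trend and robust, amitriptyline had 28, citalopram 3, imipramine 17, the mean 50 and the F test 32. With array weights amitriptyline had 222, citalopram 76, imipramine 128, mirtazapine 110, the mean 181 and the F test 0. Quantile normalized again, amitriptyline had 18, imipramine 18 (14 higher, against 5 of 5 in the reported fit), mirtazapine 348 (82 higher, against 47) and the mean 25, and the lysosome median under amitriptyline was 0.019. Without both arrays that stand apart, amitriptyline had 228, imipramine 84, the mean 206, the F test 0 and the lists 46 shifts. With only the 4 arrays compared, imipramine had 0 and mirtazapine 14. List shifts numbered 52 with camera's preset correlation, 0 with an estimated correlation and 10 with fry. Replicates 1 and 2 of different groups share only a number. With that number as a replicate block, imipramine had 3 calls, mirtazapine 234, the mean 1 and the F test 0, and the deviations of replicates correlated between −0.44 and 0.71 over 15 pairs of groups. Leaving out 1 array at a time, calls ranged from 0 to 48 for amitriptyline, 0 to 10 for citalopram, 0 to 2040 for duloxetine, 0 to 29 for imipramine, 0 to 1450 for mirtazapine, 0 to 243 for the mean, 0 to 76 for the F test and 47 to 58 for list shifts, with 0 throughout for amitriptyline against imipramine. These list medians changed sign or reached 0 without control replicate 1, here with their range over single arrays left out: immediate early under amitriptyline (−0.168 to 0.008), citalopram (−0.103 to 0.05) and imipramine (−0.083 to 0.077), cholesterol under duloxetine (−0.03 to 0.205), lysosome under imipramine (0 to 0.087), and microglia under amitriptyline (−0.11 to 0.095), citalopram (−0.155 to 0.077) and imipramine (−0.113 to 0.062). Lysosome under amitriptyline (−0.038 to 0.055), at 0 in the reported fit, left 0 with a call without control replicate 2, and interferon and inflammation under imipramine (−0.005 to 0.095) changed sign without imipramine replicate 1. Signal over background limits dim genes: 4713 named genes lay below the filter.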

Other observations

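The tests of the explanations below were chosen after the results were seen. The 20 cholesterol synthesis genes had positive medians under every drug: 0.21 under amitriptyline, 0.18 under citalopram, 0.10 under duloxetine, 0.20 under imipramine and 0.18 under mirtazapine. Camera's adjusted p were 1.71e-08, 5.83e-09, 0.0219, 1.11e-07 and 0.000498, and adjusted p were 0.507, 0.507, 0.904, 0.544 and 0.742 with an estimated correlation. Of its members the lanosterol synthase gene Lss rose under mirtazapine (0.53, adjusted p = 0.049), and the squalene epoxidase gene Sqle lay between 0.04 and 0.18 without passing. All 5 calls ended without control replicate 1 (medians 0.04, 0.06, −0.03, 0.02 and 0.03), and that under duloxetine also without duloxetine replicate 1 (0.03), that under mirtazapine without mirtazapine replicate 1 (0.14). Unfolded protein response genes of the endoplasmic reticulum had medians of 0.09, 0.13 and 0.15 under amitriptyline, citalopram and imipramine (camera adjusted p = 0.000904, 0.00021 and 3.94e-08, and adjusted p = 0.616, 0.544 and 0.4 with an estimated correlation), and the first call ended without control replicate 1 (0.04). Over the alternatives the median under citalopram ranged from 0.042 to 0.157 and that under imipramine from 0.105 to 0.205. In the interferon and inflammation list the genes that rose adjusted over the list alone under imipramine were Ptgs2, the chemokine genes Cxcl1 (1.20) and Cxcl10 (0.65) and the iron-binding protein gene Lcn2 (0.89), while the median was 0.04 (camera adjusted p = 0.0112, and adjusted p = 0.622 with an estimated correlation). That call ended without control replicate 2 (0.02), and without imipramine replicate 1 the median was −0.01. Camera also called the interferon and inflammation list higher under amitriptyline (median 0.055, adjusted p = 0.0175), citalopram (0.065, adjusted p = 0.00251) and mirtazapine (0.12, adjusted p = 0.00291). With an estimated correlation it called none of these. In the glycolysis and hypoxia list, which camera did not call under mirtazapine (median −0.16, adjusted p = 0.391), the glucose transporter gene Slc2a1 (0.64), Pfkfb3 (0.41) and Vegfa (0.55) rose and Egln3 (−1.04) and Tpi1 (−0.49) fell over all genes.

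Duloxetine replicate 2 and mirtazapine replicate 2 stood apart from the other 10 arrays. A compressed signal range alone would leave their residuals near those of the others after a straight-line fit, but the lower of their residual SDs was 1.71 times the highest elsewhere, which argues against it as the whole cause. The drugs themselves would set replicate 1 apart too. The residual SD of those arrays was at most 0.156, against 0.174 for control replicate 1, the highest array of the other groups. The remaining arrays of those groups lay lower, at 0.099 to 0.134, so this comparison rests on 1 control array and does not exclude a part played by the drugs. Replicate 1 of duloxetine (0.155) and of mirtazapine (0.156) still lay well below replicate 2 (0.298 and 0.301), which argues against the drugs as the whole cause. A difference in culture, RNA or hybridisation of these arrays may remain and was not tested, since the labels give no batch.

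Cell cycle genes and astrocyte markers were lower under 4 drugs than in control. If a chance deviation of the shared control arrays were the cause, the difference from duloxetine would reach 0, but the highest upper 95% bound of these list means against duloxetine was −0.01, a narrow margin, and −0.11 without both arrays that stand apart. Of the means set against control here, the arrays that stand apart enter only that of mirtazapine, beside the pooled spread, and without them the highest upper bound of its list means against control was −0.20. Fewer dividing cells, progenitors and astrocytes, or lower transcript levels per cell, may both remain as hypotheses, and neither was tested. The pattern itself was found and tested on the same data.

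Ptgs2, Ostn, Cxcl2, Hmox1 and Ier3, which rose under imipramine, were higher under the other 3 drugs too, and not under duloxetine. Against duloxetine, where no control mean enters, the lowest of their lower 95% bounds over the 4 drugs was 0.55, which argues against a chance deviation of the shared controls as the whole cause, though the pattern was named with duloxetine already seen. Genes were also picked as rising under imipramine against 1 control array, 5 for each array, and measured against the other under amitriptyline, citalopram and mirtazapine. The 3 intervals of a gene share that other control array and are not independent, and Ostn, Hmox1 and Ptgs2 were picked against both. Above 0 lay 15 of 15 intervals for genes picked against control replicate 1, and 12 of 15 for control replicate 2. The exception was Lilrb4a (lowest bound −1.08), which is not among the called genes, so a deviation of 1 control array stays open for genes picked that way, while the called genes among those picked, Cxcl2 not being one, had bounds of at least 0.38. The lower dose of duloxetine may account for its difference, and dose and drug cannot be told apart, since the design has 1 dose of duloxetine.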
